A study of Homo sapiens with 48 samples.

How the data were processed

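The 48 libraries were RNA sequencing libraries of polyadenylated RNA from 4 human lung cancer cell lines, with 3 libraries for each of 4 treatments per line. Groups were taken from the cell line and treatment labels, and the concentration of 0.1 µM for each drug from the series text. Replicates were numbered in the order of their records, so the numbers name libraries and pair none. The extraction text of the labels describes brain cells rather than cultured lines, and nothing was taken from it.

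Each deposited file held 2 values per gene. The authors' raw counts were, per the file headers, reads that aligned uniquely to each gene model. The second value was an RPKM that the authors had divided by a library size factor, per the file headers, and how that factor was made is not given in the sources used here. The deposited RPKM values were checked against the counts on 7953 genes, where they equalled count over length and depth over a size factor of 0.71 to 1.42 with a largest absolute log2 residual of 1.1e-14, and they were not used further. GSNAP and the build GRCh37 are named, per the submitters' processing notes, and versions, gene annotation and strand use are not given in the sources used here. Reads aligning to more than 1 place were left out by the authors' counting, so genes with near-identical copies are undercounted. Of 26468 gene IDs, 1221 had counts identical to those of another ID in every library (812 of them with a symbol), and these held 1.09% of the counts. Without stated strand use, reads of overlapping antisense genes cannot be told apart.

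Gene IDs were matched to symbols in a reference table of the assembly GRCh38.p14. As this is another build than the authors', it served for names only and no coordinates are given. A symbol was found for 24519 IDs (92.6%), which held 97.82% of the counts. The remaining 2.18% stayed in the tests and in library sizes.

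Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter at a minimum count of 10 and robust quasi-likelihood fitting of 16 group means over all 48 libraries. This left 17981 genes, 32 residual degrees of freedom and a median of 9.89 prior degrees of freedom. All groups share 1 estimate of spread per gene in this fit, and the median gene SD of log2 CPM was 0.12 in A549, 0.13 in NCI-H1792, 0.14 in NCI-H2122 and 0.09 in NCI-H727. Contrasts were each treatment against DMSO, the combination against each single drug, GDC-0973 against AZ-628, and the departure from additivity (combination minus GDC-0973 minus AZ-628 plus DMSO, log2), in each line and, except for comparisons between treated groups, averaged over the lines. Differences of response between lines were tested by an F test over 3 contrasts. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. Log2 changes are edgeR's. Their SEs come from the spread of log2 CPM (prior count 2) between the 3 libraries of each group, and adjusted p-values from the edgeR fit. CPM values use the TMM library sizes.

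The 28 gene lists, the design and its alternatives were fixed before the data were examined. The lists were the MAPK activity score, other ERK-induced genes, DNA replication and E2F targets, mitosis, CDK inhibitors and quiescence, pro-apoptotic and anti-apoptotic BCL2 family genes, receptor tyrosine kinases and adaptors, RAS-RAF-MEK-ERK components, interferon-stimulated genes, MHC class I presentation, NF-kB cytokines, YAP-TEAD targets, mesenchymal, epithelial, alveolar and foregut, and neuroendocrine genes, glycolysis, cholesterol synthesis, the integrated stress response, NRF2 targets, lysosome and autophagy, ribosome biogenesis, p53 targets, markers of fibroblasts, immune cells and brain cells, and the mitochondrial genome. Lists with at least 3 tested members were tested with limma 3.58.1, by camera with the correlation between genes estimated from the data and Benjamini-Hochberg adjustment over the lists of a contrast. A preset correlation of 0.01 and the fry test were alternatives. Counts of members called are given over all genes and adjusted over the list alone.

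Named genes followed a rule. They had a mean log2 CPM of at least 1, and were the 10 largest average rises and 10 largest falls with the combination among genes called the same way in all 4 lines and in the average, the 5 largest called in each direction on average for each single drug and for the departure from additivity, and in each line the 3 largest in each direction with the combination and the 2 largest for comparisons between treated groups, where all 3 libraries of 1 group lay beyond all 3 of the other. The MAPK score genes, the drug target genes MAP2K1, MAP2K2, ARAF and BRAF, and the 2 largest called members of a described list in each direction were added. Some genes that the rule takes are not reported here. NDRG1, the upward departures in A549 and NCI-H1792, the leading genes of AZ-628 in NCI-H727 and of GDC-0973 in NCI-H2122, and genes given in place of trace genes were named after their values were seen. A gene was termed a trace gene of a line where its mean level there was under 1% of that in the highest line. For these, counts are given, with a ratio of group sums and its exact 95% interval for the combination against DMSO where neither sum was 0. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

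The MAPK activity score of a library was the mean log2 CPM of its 10 genes. It was compared by exact two-sided permutation, in each line over 20 assignments and over the lines by permuting treatments within lines over 160000 assignments. Its line differences were tested over 15400 assignments to lines of the 12 treated libraries, each as its change from the DMSO mean of its line. The 3 libraries of a line share the error of that mean, so they are not fully exchangeable and these p-values are too small.

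Replicate pairs were compared by a chi-square per gene of their counts, which was 1.71 to 22 over the 48 pairs, so no pair agreed within sampling noise and all libraries were counted separately. The lowest values were those of NCI-H727, with 2.74, 2.66 and 1.75 for its DMSO pairs and up to 12.7 with both drugs. In the other lines the lowest was 6.44, so replicates of NCI-H727 were mostly closer to each other. At the depth of 16886878 to 35564081 counts per library, the procedure was tested on simulated data with the real means and library sizes over 17981 genes. For the combination in A549 it recovered 75.0, 92.4 and 93.9% of genes changed 1.5, 2 and 4 times, and 3.33% of its calls were false. For GDC-0973 in NCI-H2122 the shares were 67.6, 87.9 and 87.9% with 3.57% false, and for the departure from additivity in A549 48.5, 80.3 and 90.9% with 1.35% false. Changed genes were drawn above a floor of mean CPM, and libraries were independent with a dispersion per gene common to all lines. The larger spread of NCI-H2122 (median gene SD 0.14) was thus not simulated, and its recovery may be lower.

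Alternatives were RLE scaling, no filter (24140 genes), DESeq2 1.42.0, a fit of each line's 12 libraries alone, 1 surrogate variable from sva 3.50.0, leaving out each library, and for the score a prior count of 0.5, RLE scaling, the median and leaving out each gene. Fits without a library kept the tested genes and the dispersion trend of the full fit. Correlations between lines were also computed as Spearman's and over genes with a mean log2 CPM of at least 3. Added after seeing the data were the 12 libraries of a line with 1 surrogate variable, only the 17096 tested gene IDs with a symbol, and a count without trace genes. Transcripts specific to a line were those at 100 CPM or more there with a median under 0.2% of that level in the line examined and means under 10% of it in the other lines.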

Results

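RNA sequencing read counts were examined for 48 libraries of polyadenylated RNA from 4 human lung cancer cell lines, A549, NCI-H1792, NCI-H2122 and NCI-H727. NCI-H727 comes from a bronchial carcinoid. Each line was treated with the vehicle DMSO, with GDC-0973 (cobimetinib, an inhibitor of the kinase MEK), with AZ-628 (an inhibitor of the RAF kinases) or with both drugs, each at 0.1 µM. This gave 16 groups of 3 libraries, so that n = 3 for every group mean and SD below. Library totals ran from 16886878 counts, in NCI-H727, to 35564081 counts, in a DMSO library of NCI-H2122, with a median of 24761642. The treatment time is not given in the sources used here. The single-drug libraries are labelled AZ638 where the series text writes AZ-628, and they were taken as AZ-628. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The most similar other library was of the same cell line for 48 of 48 libraries and of the same line and treatment for 21 of 48. Correlation of log2 CPM was at least 0.993 within a group and at most 0.865 between lines.

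The first comparison asked what the combination of both drugs did to each line against DMSO. In all 4 lines the combination lowered the transcripts of feedback inhibitors and transcription factors that are switched on by ERK, and raised BMF, a pro-apoptotic member of the BCL2 family. DUSP6 (gene ID 1848), the phosphatase that inactivates ERK, fell from 12.5 ± 2.24 CPM (SD, n = 3) to 0.429 ± 0.0759 in A549, from 19.8 ± 4.23 to 0.782 ± 0.157 in NCI-H1792, from 53.7 ± 13.6 to 6.61 ± 1.89 in NCI-H2122 and from 485 ± 18.9 to 23.0 ± 1.33 in NCI-H727. BMF (gene ID 90427) rose from 2.20 ± 0.504 to 9.38 ± 1.94 CPM, from 5.20 ± 1.63 to 48.3 ± 4.52, from 14.9 ± 4.36 to 48 ± 19.4 and from 41.0 ± 0.516 to 174 ± 9.73 in the same order of lines. In log2 units averaged over the lines, DUSP6 changed by -4.22 ± 0.12 (SE; adjusted p = 3e-24) and BMF by 2.27 ± 0.14 (adjusted p = 1.5e-16).

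Among genes that fell in every line, the average log2 changes were -4.33 ± 0.17 for SPRY4 (gene ID 81848), an inhibitor of receptor to RAS signalling, and -3.16 ± 0.10 for ETV5 (gene ID 2119), an ETS family transcription factor (adjusted p = 8.9e-29 and 4.5e-30). SPRY4 in A549 went from 11.8 ± 0.835 to 0.134 ± 0.123 CPM. The latter is near the floor of counting, so fitted SPRY4 changes that use these A549 libraries, here and below, depend on the prior count and are imprecise in size. PHLDA1 (gene ID 22822) changed by -2.49 ± 0.04, the AP-1 component FOS by -2.47 ± 0.16, the small MAF factor MAFF by -2.40 ± 0.11 and the phosphatase DUSP4 by -1.98 ± 0.07. Falls also included the neutrophil chemoattractant CXCL8 (-2.53 ± 0.16), the receptor kinase EPHA2 (-2.43 ± 0.08) and ANGPTL4, an inhibitor of lipoprotein lipase (-2.19 ± 0.16). Among genes that rose in every line, SYNPO, an actin-binding protein, changed by 1.07 ± 0.06, SECTM1 by 1.01 ± 0.10, PIK3IP1, an inhibitor of PI3 kinase, by 1.0 ± 0.11 and the stress-induced factor ATF3 by 0.94 ± 0.09. CRISPLD2 and ZNF608 both rose by 0.95, with SEs of 0.13 and 0.11, and HR and the haem transporter family member FLVCR2 both by 0.91, with SEs of 0.14 and 0.07. OLFML2A rose by 1.47 ± 0.12 on average, but it was at trace level in NCI-H2122 (under 1% of its mean in the highest line), at 25 over the 3 DMSO libraries and 59 over the 3 combination libraries, a ratio of 2.85 (95% exact interval of counting error 1.76 to 4.74).

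**Figure D1:**
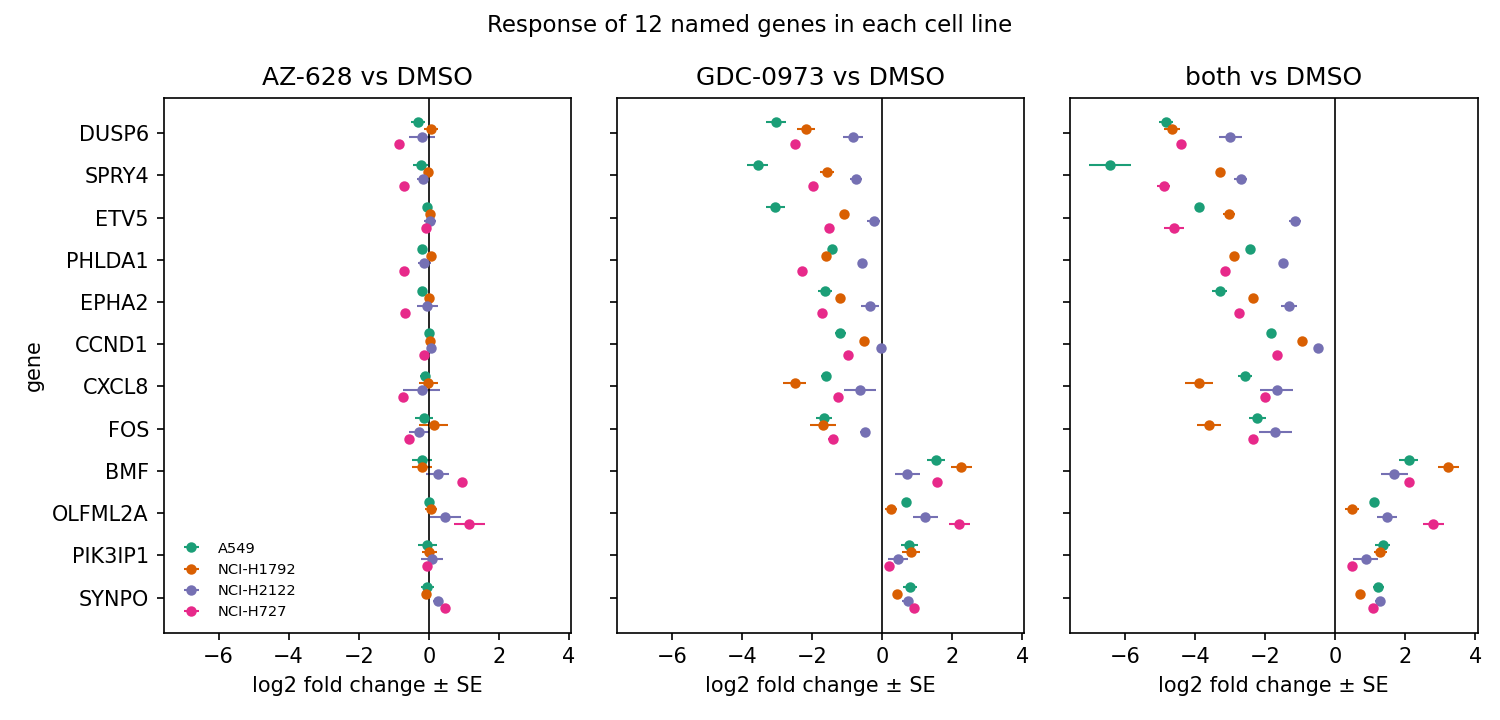
Log2 change against DMSO (x axis; points, SE as error bars) of 12 genes (y axis) in each of the 4 cell lines (colours) with AZ-628, GDC-0973 and both drugs, 1 panel per treatment, n = 3 libraries per group. With both drugs DUSP6 lies at -4.83, -4.66, -2.99 and -4.40 and BMF at 2.09, 3.23, 1.69 and 2.09 in A549, NCI-H1792, NCI-H2122 and NCI-H727, while OLFML2A in NCI-H2122 rests on trace counts.

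Of 17981 genes tested, 1408 rose and 1263 fell in A549, 1325 and 1271 in NCI-H1792, 336 and 573 in NCI-H2122, and 2400 and 2392 in NCI-H727 (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was reached by 378, 334, 109 and 721 of them. On average over the lines 2815 genes rose and 2722 fell. In all 4 lines 55 genes rose and 142 fell, while 344 genes rose in at least 1 line and fell in another. Fitted to its own 12 libraries alone, NCI-H2122 gave 358 calls in place of 909, and without its combination replicate 3 or its DMSO replicate 3 it gave 567 or 584.

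**Figure D2:**
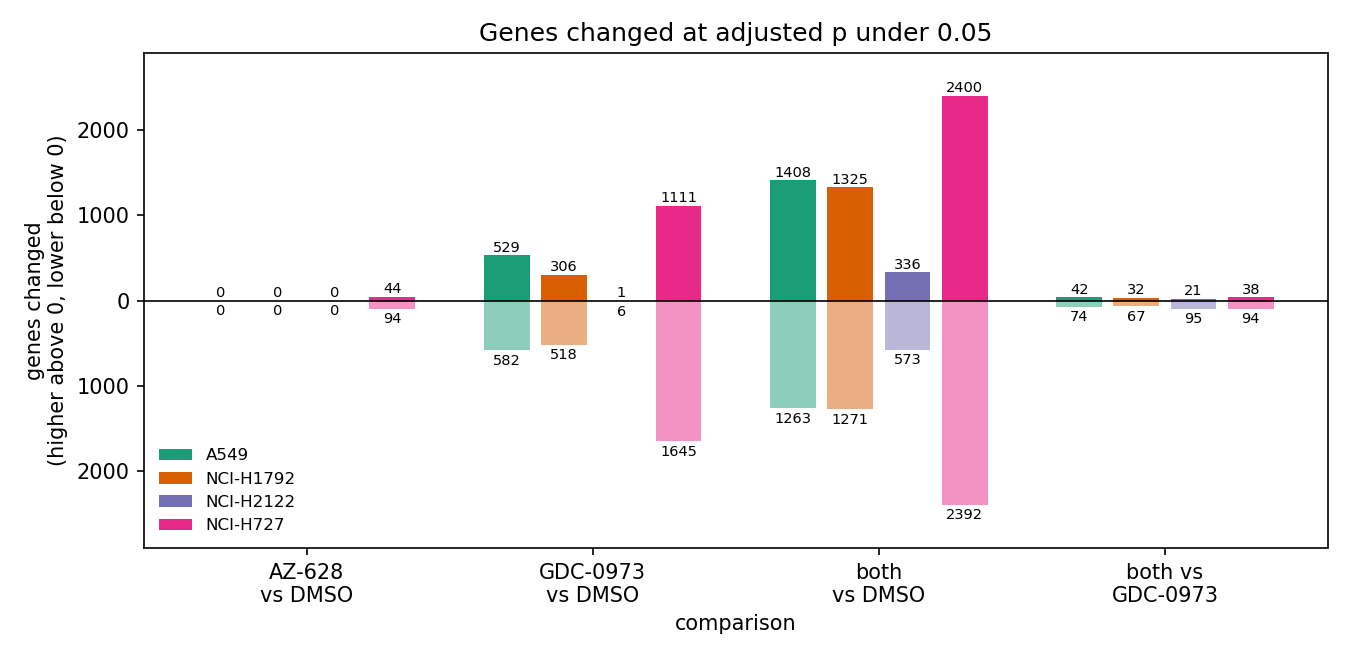
Number of genes called (y axis, bars, rises above 0 and falls below 0 in a lighter shade) for 4 comparisons (x axis) in each of the 4 cell lines (colours). The combination against DMSO gave 4792 calls in NCI-H727 and 909 in NCI-H2122, and AZ-628 against DMSO gave 138 in NCI-H727 and 0 in the other lines.

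The gene lists were fixed before the data were examined. Of the 10 genes of the MAPK activity score, a set of ERK-dependent transcripts, 10 fell on average (10 adjusted over the list alone; adjusted p = 0.00012 by the camera list test). Their falls ran from EPHA4 at -0.18 ± 0.09 to SPRY4, and included SPRY2 (-1.78 ± 0.06), the cyclin CCND1 (-1.24 ± 0.04) and ETV4 (-1.35 ± 0.07). EPHA4 lost its call without any 1 of 7 libraries, rose by 1.12 in A549 and changed by -1.52 in NCI-H727. Of 20 other ERK-induced genes, 18 fell (19 adjusted over the list alone; adjusted p = 8e-05), led by EGR1 at -2.75 and FOS. All 5 anti-apoptotic BCL2 family genes fell (5 adjusted over the list alone; adjusted p = 0.00046), with BCL2L1 at -0.81 and BCL2A1, which was at trace level in NCI-H727, at -1.28. Of 9 pro-apoptotic family members, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.37). BMF and BBC3 (0.89) rose most, and PMAIP1 (-0.62) and BID (-0.09) fell.

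Of 14 ribosome biogenesis genes, 13 fell (13 adjusted over the list alone), among them RRP12 (-0.51) and RRP9 (-0.50), and the list had an adjusted p = 0.067 with an estimated correlation and 8.9e-12 with a preset one. Of 12 CDK inhibitors and quiescence genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.073 with an estimated correlation). CDKN1C, an inhibitor of cyclin-dependent kinases, changed by 1.20, the cyclin CCNG2 by 0.67 and BTG1 by -0.16. In A549 that list passed its test with 7 rises and no fall among 12 genes (9 adjusted over the list alone; adjusted p = 0.0019). Of 15 mitosis genes, 8 rose and none fell (8 adjusted over the list alone; adjusted p = 0.55 with an estimated correlation), with CENPF at 0.23 and CCNB2 at 0.21. Of 20 DNA replication and E2F target genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.77), with TK1 at 0.17, MCM5 at 0.14, CDC25A at -0.45 and CCNE1 at -0.37.

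Among signalling and surface genes, 7 of 17 receptor tyrosine kinases and adaptors rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.79). FGFR2, at trace level in NCI-H1792, changed by 0.74, FGFR3 by 0.61, the insulin receptor substrate IRS2 by -0.82 and EGFR by -0.49. Of 19 components of the RAS-RAF-MEK-ERK cascade, 3 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.92), with SOS1 at 0.26, SOS2 at 0.21, RASA2 at -0.35 and NF1 at -0.16. Among genes of the drug targets, MAP2K1 fell by 0.12 ± 0.02 on average (adjusted p = 0.00024), while MAP2K2 (0.06), ARAF (0.02) and BRAF (-0.06) were not called. Of 11 NF-kB cytokine genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with CXCL1 at -1.42 beside CXCL8, and NFKBIA at 0.12. Of 11 YAP-TEAD targets, 2 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation), with CCN2 at -1.83, NT5E at -1.22, AJUBA at 0.49 and LATS2 at 0.12.

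Further genes were named for single lines. In A549 the transcription cofactor ARID5B changed by 1.94 and the thyroid hormone deiodinase DIO2 by 1.84, both called. In NCI-H1792 EGR1 changed by -4.22, CXCL8 by -3.89, the circadian factor DBP by 2.12 and the anticoagulant protease PROC by 1.84. NCI-H2122 lost RASD1, a RAS-related GTPase (-2.16), and gained SYNPO (1.27) and the helix-loop-helix factor ATOH8 (1.1). In NCI-H727 OLFML2A changed by 2.80 and the forkhead factor FOXP2 by 2.47. Other genes with large fitted changes had mean levels under 1% of those of another line and are given as counts. In NCI-H1792, NTS had 0, 0 and 0 counts with DMSO and 39, 1 and 154 with the combination, KIF12 0, 0 and 0 and then 6, 1 and 22, and VIL1 2, 1 and 1 and then 32, 4 and 92 (ratio of sums 32.9, interval 12.6 to 123). All 3 are highest in NCI-H727. In the NCI-H1792 combination libraries, 46 transcripts specific to NCI-H727 stood at a median of 0.126, 0.0116 and 0.413% of their NCI-H727 level in replicates 1, 2 and 3. They stood at no more than 0.0201% in the 9 other NCI-H1792 libraries. S100A9 in NCI-H1792 had 167 counts with DMSO and 1 with the combination (ratio 0.00616, interval 0.000155 to 0.0348), and TRIM29 had 32 and 1 (ratio 0.0322, interval 0.00079 to 0.193). Both are highest in NCI-H2122, and 17 transcripts specific to that line stood in the NCI-H1792 DMSO libraries at a median of 0.0508, 0.118 and 0.215% of their NCI-H2122 level, in GDC-0973 replicate 2 at 0.166% and in the other libraries at no more than 0.0193%. S100A9 had 27, 67 and 73 counts in those DMSO libraries, 0, 70 and 0 with GDC-0973 and 0 in each AZ-628 library. In NCI-H2122, MMP2 went from 4 to 88 counts (ratio 26.5, interval 10 to 99.6), FOXL1 from 1 to 12 (ratio 14.5, interval 2.14 to 619) and ANKRD1 from 2 to 16 (ratio 9.65, interval 2.27 to 86.5). All 3 are highest in NCI-H1792, and 16 transcripts specific to that line stood in the NCI-H2122 combination libraries at a median of 0.0705, 0.0438 and 0.171% of their NCI-H1792 level and in the 9 other libraries at no more than 0.0407%, beside MMP2 counts of 24, 8 and 56. ANKRD1 had 6, 2 and 8 counts in these libraries, 1, 1 and 0 with DMSO and 3, 5 and 4 with GDC-0973, where the NCI-H1792 share was no more than 0.0407%. The calls of MMP2, FOXL1 and ANKRD1 ended without combination replicate 3 (adjusted p = 0.092, 0.33 and 0.18), and those of FOXL1, ANKRD1 and TRIM29 without any 1 of 3, 5 and 5 libraries. In NCI-H727, GLI2, which is highest in A549, went from 4 to 36 counts (ratio 9.08, interval 3.25 to 35.1). It had 1, 3 and 0 counts with DMSO, 2, 8 and 7 with AZ-628, 3, 4 and 10 with GDC-0973 and 9, 16 and 11 with both. In the same libraries 7 transcripts specific to A549 stood at a median of 0.0931, 0.522 and 0.086% of their A549 level with both drugs, at 0.208% in AZ-628 replicate 3, at 0% in the 3 GDC-0973 and the other AZ-628 libraries and at no more than 0.0375% with DMSO.

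The MAPK activity score, the mean log2 CPM of its 10 genes per library, gave 1 value for the pathway's transcriptional output. With DMSO it was 5.34 ± 0.13 in A549, 5.95 ± 0.10 in NCI-H1792, 5.91 ± 0.13 in NCI-H2122 and 7.41 ± 0.05 in NCI-H727 (SD). With the combination it was 2.51 ± 0.22, 3.78 ± 0.04, 4.58 ± 0.18 and 4.55 ± 0.09. The differences were -2.84, -2.16, -1.33 and -2.86, with SEs of 0.15, 0.06, 0.13 and 0.06, and their mean was -2.30 ± 0.05. An exact two-sided permutation test within lines gave p = 1.3e-05 for that mean, the smallest value that its 160000 assignments can give. Within 1 line the 20 assignments cannot give a p under 0.1.

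**Figure D3:**
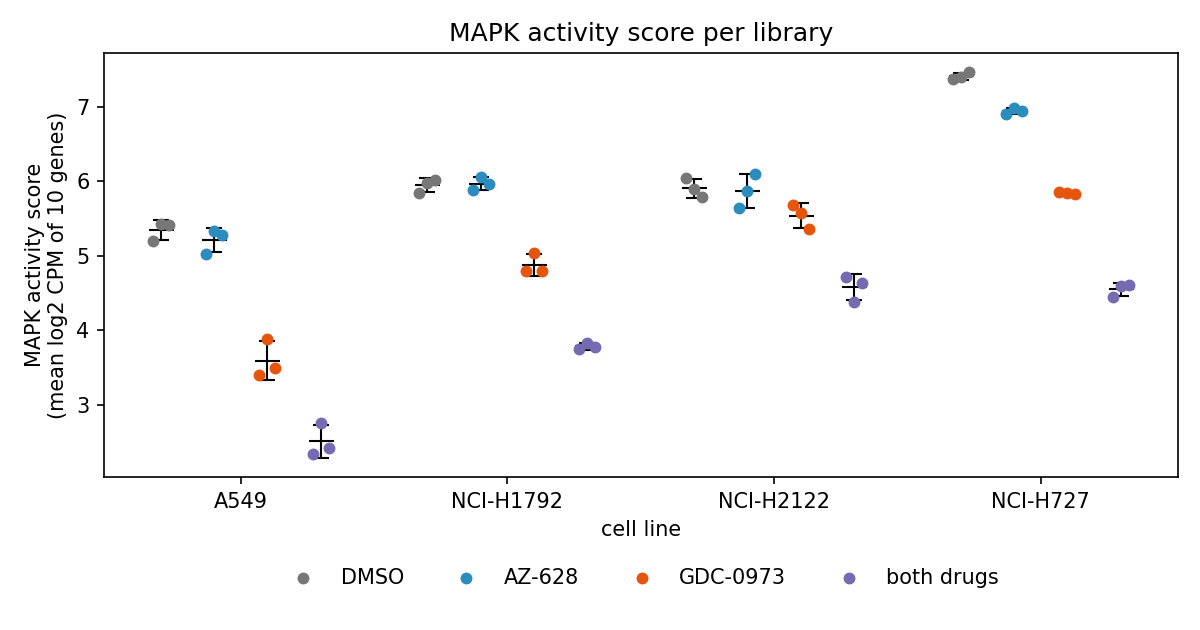
MAPK activity score per library (y axis, mean log2 CPM of 10 genes) for 4 treatments (colours) in each of 4 cell lines (x axis), with points for libraries and black marks for the mean and SD of 3 libraries. The score with both drugs lies lowest in every line, at means of 2.51 to 4.58, and with AZ-628 alone it stays near the DMSO mean in A549, NCI-H1792 and NCI-H2122.

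GDC-0973 alone was compared with DMSO to show the effect of MEK inhibition by itself. Feedback genes of the ERK pathway fell and BMF rose, with smaller average changes than with both drugs. On average over the lines DUSP6 changed by -2.12 ± 0.12, SPRY4 by -1.96 ± 0.10, the early response factor EGR1 by -1.88 ± 0.27, CXCL8 by -1.50 ± 0.14 and PHLDA1 by -1.47 ± 0.04. BMF rose by 1.53 ± 0.13 (adjusted p = 5.5e-11), OLFML2A by 1.09 ± 0.13, TP53INP1, a p53-induced regulator of autophagy and cell death, by 0.83 ± 0.11, and the basement membrane collagen COL4A3 by 0.81 ± 0.11. DIO2, at trace level in NCI-H727, was called at 0.98 ± 0.20 (adjusted p = 0.017), a call that ended without GDC-0973 replicate 2 of NCI-H727 (0.83). In NCI-H2122 the changes of DUSP6 (-0.82, adjusted p = 0.14), SPRY4 (-0.74, adjusted p = 0.058) and BMF (0.72, adjusted p = 1) were not called, against -3.02, -3.55 and 1.55 in A549, which were. PHLDA1 fell in that line, from 269 ± 22.4 to 182 ± 16.5 CPM, and SYNPO rose by 0.73.

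With GDC-0973 alone, 529 genes rose and 582 fell in A549, 306 and 518 in NCI-H1792, 1111 and 1645 in NCI-H727, and 1 and 6 in NCI-H2122. The test of the average over the lines called 1292 rises and 1642 falls. The only gene that rose in all 4 lines was SYNPO, and the only gene that fell in all 4 was PHLDA1. Of the 10 MAPK activity score genes, 9 fell on average (9 adjusted over the list alone; adjusted p = 9.4e-05), and of the 20 other ERK-induced genes 19 fell (19 adjusted over the list alone; adjusted p = 6.8e-05), FOS by 1.31. Of 5 anti-apoptotic BCL2 family genes, 3 fell (5 adjusted over the list alone; adjusted p = 0.0023), with BCL2L1 at -0.47 and MCL1 at -0.41. Ribosome biogenesis genes fell in 12 of 14 cases (14 adjusted over the list alone; adjusted p = 0.043), with RRP12 and RRP9 both at -0.39. CDK inhibitors and quiescence genes rose in 3 of 12 cases (3 adjusted over the list alone; adjusted p = 0.13), with CCNG2 at 0.48 and CDKN2C at 0.41. In A549 that list passed its test with 5 rises (6 adjusted over the list alone; adjusted p = 5e-04). In NCI-H2122, 1 MAPK score gene fell (4 adjusted over the list alone) and none of the 20 other ERK-induced genes did (4 adjusted over the list alone; adjusted p = 0.047 for both lists).

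The MAPK activity score fell with GDC-0973 by 1.75 in A549, by 1.07 in NCI-H1792, by 0.37 in NCI-H2122 and by 1.57 in NCI-H727, with SEs of 0.17, 0.10, 0.12 and 0.03, and the mean difference was -1.19 ± 0.06 (exact permutation p = 1.3e-05, two-sided). The 7 calls in NCI-H2122 compare with 11 by DESeq2 and 0 when that line was fitted alone. There 611 genes (3.4%) had an unadjusted p under 0.05, less than the share of 0.05 that genes without change would give. The p-values thus ran large in that line, so the few calls do not show that few genes changed. Without GDC-0973 replicate 1 the call counts were 655 in A549 and 515 in NCI-H1792, and without DMSO replicate 2 the NCI-H1792 count was 535.

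AZ-628 alone was compared with DMSO to show the effect of RAF inhibition by itself. Calls were found in NCI-H727, with 44 rises and 94 falls. In A549, NCI-H1792 and NCI-H2122 edgeR called 0 genes, and DESeq2 called 0, 14 and 0. By edgeR 334, 436 and 373 genes had an unadjusted p under 0.05. These are 1.86, 2.42 and 2.07% of the genes tested, less than the share of 0.05 that genes without change would give. The p-values thus ran large in these lines, so the lack of calls does not show a lack of change. In NCI-H727 the ERK targets DUSP6 (-0.85 ± 0.04), ERRFI1, a feedback inhibitor of EGFR (-0.80), SPRY4 (-0.71), PHLDA1 (-0.70), EPHA2 (-0.67) and DUSP4 (-0.63) fell. BMF rose there by 0.95 ± 0.02 (adjusted p = 0.017). DUSP6 in NCI-H727 stood at 269 ± 6.60 CPM with AZ-628, 86.1 ± 2.05 with GDC-0973 and 485 ± 18.9 with DMSO. Rises in NCI-H727 also included FOXP2 and ATOH8 (both 1.1), the cytochrome P450 gene CYP1B1 (1.05 ± 0.15) and TIPARP, a PARP family member induced by the aryl hydrocarbon receptor (0.70), and falls included FJX1 (-0.97) and the WNT inhibitor DKK1 (-0.89).

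Averaged over the lines, AZ-628 raised 4 genes and lowered 6. CYP1B1 changed by 0.42 ± 0.10 (adjusted p = 0.021), the MAP kinase kinase MAP2K6 by 0.34 ± 0.05, TIPARP by 0.25 ± 0.06, the phosphatase DUSP16 by 0.18 ± 0.03, FJX1 by -0.26 ± 0.04, PHLDA1 by -0.24 ± 0.06, ERRFI1 by -0.23 ± 0.06, the stress kinase PLK2 by -0.21 ± 0.03, YRDC by -0.18 ± 0.02 and MYC by -0.15 ± 0.03. Of these, CYP1B1, TIPARP, DUSP16, ERRFI1 and YRDC lost their calls without any 1 of 7, 12, 21, 20 and 16 libraries. By the F test of the difference between lines, 7 of the 10 (TIPARP, DUSP16, FJX1, PHLDA1, ERRFI1, PLK2 and MYC) responded differently, all 7 being called in NCI-H727 and in no other line, as FJX1 at -0.97 in NCI-H727 and at 0, -0.05 and -0.02 in A549, NCI-H1792 and NCI-H2122. In NCI-H727, 5 of 10 MAPK score genes (7 adjusted over the list alone; adjusted p = 0.012) and 4 of 20 other ERK-induced genes fell (11 adjusted over the list alone; adjusted p = 0.0054). Averaged over the lines, 1 gene of each list fell (5 and 4 adjusted over the lists alone), with adjusted p = 0.33 and adjusted p = 0.22 with an estimated correlation. The MAPK activity score differed from DMSO by -0.46 ± 0.04 (SE) in NCI-H727 and by -0.13, 0.02 and -0.04 in A549, NCI-H1792 and NCI-H2122, and the mean difference was -0.15 ± 0.05 (exact permutation p = 0.028, two-sided). That p was above 0.05 without AZ-628 replicate 1 of A549 (0.051) and without AZ-628 replicate 1 (0.066) or DMSO replicate 1 (0.058) of NCI-H2122. In NCI-H727 the 138 calls became 220 with DESeq2, 490 with the line fitted alone and 72 to 95 without any 1 of the 6 libraries.

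The combination was compared with each single drug to show what the second drug added. Adding AZ-628 to GDC-0973 lowered the ERK targets further in each line. DUSP6 changed by -2.49 in NCI-H1792, -2.17 in NCI-H2122 and -1.90 in NCI-H727, all called, and by -1.81 in A549 (adjusted p = 0.13). SPRY4 changed by -2.88 ± 0.67 in A549, where it was near the floor of counting with both drugs, -1.96 in NCI-H2122 and -2.92 in NCI-H727. ETV5 changed by -1.94 in NCI-H1792 and -3.09 in NCI-H727. PHLDA1 in NCI-H2122 went from 182 ± 16.5 to 96.4 ± 1.41 CPM. BMF rose by 0.97 in both NCI-H1792 (adjusted p = 0.025) and NCI-H2122 (adjusted p = 0.023).

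Against GDC-0973 alone, 42 genes rose and 74 fell in A549, 32 and 67 in NCI-H1792, 21 and 95 in NCI-H2122, and 38 and 94 in NCI-H727. Without any 1 library the totals of 116, 99, 116 and 132 ranged from 36 to 138, 44 to 138, 46 to 167 and 67 to 178, and another split of the 6 A549 libraries gave 100. MAPK activity score genes fell in 7, 8, 9 and 9 of 10 cases in that order of lines (8, 9, 9 and 10 adjusted over the list alone; highest adjusted p = 0.00013). Of the 20 other ERK-induced genes 5, 7, 7 and 7 fell, and 1 rose in NCI-H1792 (10, 11, 12 and 10 falls adjusted over the list alone; highest adjusted p = 0.0049). In A549 EPHA2 fell by 1.67 and the phosphatase DUSP8 rose by 0.95. In NCI-H1792 MAP2K6 rose by 0.85, in NCI-H2122 the kinase DYRK3 by 0.74, and in NCI-H727 CYP1B1 and the GTPase MRAS both by 0.78. The score differed by -1.08, -1.10, -0.96 and -1.29, a mean of -1.11 ± 0.07 (exact permutation p = 1.3e-05, two-sided). The A549 calls of SPRY4 and DUSP8 ended without single libraries (-2.24 for SPRY4 without combination replicate 1 and -2.50 without GDC-0973 replicate 2; 0.91 and 0.92 for DUSP8 without GDC-0973 replicates 1 and 2, and 0.83 without combination replicate 2). Fitted alone, NCI-H727 gave 991 calls, 50.1% of them upward in place of 28.8%, and NCI-H2122 gave 20, none of them upward.

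Against AZ-628 alone, the combination raised 1481 and lowered 1223 genes in A549, 1135 and 1110 in NCI-H1792, 191 and 480 in NCI-H2122, and 1426 and 1776 in NCI-H727. BMF rose by 2.29, 3.43 and 1.44 in A549, NCI-H1792 and NCI-H2122. DUSP6 changed by -4.52, -4.72 and -2.79 in those lines, SPRY4 by -6.19 in A549, -2.54 in NCI-H2122 and -4.18 in NCI-H727, CXCL8 by -3.88 in NCI-H1792 and ETV5 by -4.53 in NCI-H727. ARID5B rose by 2.03 in A549, DBP by 1.73 in NCI-H1792, the phospholipase PLCE1 by 1.11 in NCI-H2122, and OLFML2A by 1.65 and FOXP2 by 1.37 in NCI-H727. The score differed by -2.70, -2.18, -1.29 and -2.40, a mean of -2.14 ± 0.06 (exact permutation p = 1.3e-05, two-sided). Fitted alone, NCI-H2122 gave 253 calls and NCI-H727 gave 5465, and single libraries moved counts by over 1.5 times without AZ-628 replicate 2 in A549 (1791), AZ-628 replicate 3 in NCI-H2122 (392) and combination replicate 3 in NCI-H727 (2072).

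The single drugs were also compared with each other at their equal concentration. ERK targets were lower with GDC-0973 than with AZ-628 in A549, NCI-H1792 and NCI-H727. SPRY4 differed by -3.32 and ETV5 by -3.0 in A549, CXCL8 by -2.48 and DUSP6 by -2.23 in NCI-H1792, and the calcium regulating hormone STC1 by -2.18 and thrombomodulin, THBD, by -1.78 in NCI-H727. BMF was higher with GDC-0973 by 1.74 in A549 and 2.46 in NCI-H1792, DIO2 by 1.49 in A549, ZSCAN31 by 1.12 in NCI-H1792, and COL4A3 by 1.21 and FOXP2 by 1.12 in NCI-H727. Genes higher and lower with GDC-0973 numbered 484 and 486 in A549, 255 and 529 in NCI-H1792, 281 and 795 in NCI-H727, and 0 and 3 in NCI-H2122. In that last line DESeq2 called 4, and 545 genes (3.03%) had an unadjusted p under 0.05 by edgeR, less than the share of 0.05 without change. The p-values of edgeR thus ran large there too. The 3 were RASD1 (-0.75), the membrane protein MCTP1 (-0.50) and the stress-responsive NDRG1, the last of which was named after its value was seen. The score differed by -1.62, -1.09, -0.33 and -1.10, a mean of -1.04 ± 0.06 (exact permutation p = 2.5e-05, two-sided). The NCI-H2122 calls of RASD1 and MCTP1 ended without any 1 of 5 and of 6 libraries.

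Departure from additivity, the change with both drugs minus the sum of the changes with each drug on the log2 scale, asked whether the drugs together did more than their separate effects add up to. On average over the lines the called genes with the largest downward departures included ERK feedback genes. SPRY4 departed by -2.09 ± 0.21 (adjusted p = 1.1e-10), DUSP6 by -1.77 ± 0.17 (adjusted p = 3.3e-07), ETV5 by -1.69 ± 0.13 (adjusted p = 1.7e-14), the adaptor SHC4 by -1.17 ± 0.20 and SPRED1, an inhibitor of RAF activation, by -1.06 ± 0.12. The SPRY4 average includes A549, where the gene was near the floor of counting with both drugs. The largest positive departures with levels above 1% of the highest line were HSPB8 at 0.30, STARD10 at 0.27, CXXC5 at 0.24, and ARRB2 and HMG20B both at 0.22. RAB25, PRNP, SERPINB5, PPL and KRTCAP3 were also called upward, each at trace level in at least 1 line. The fitted values of RAB25 (2.89), PRNP (1.70) and SERPINB5 (1.49) were large beside those of the falls but rest on low counts in those lines, and RAB25, KRTCAP3, PRNP and SERPINB5 lost their calls without any 1 of 26, 10, 4 and 2 libraries. RAB25 counts in NCI-H1792, for example, were 4, 15 and 10 with DMSO, 0, 0 and 2 with AZ-628, 1, 9 and 1 with GDC-0973 and 5, 0 and 14 with both.

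Over the average, 12 genes departed upward and 53 downward. Of the 10 MAPK activity score genes 8 departed downward (9 adjusted over the list alone; adjusted p = 8.6e-06), and of the 20 other ERK-induced genes 7 did (11 adjusted over the list alone; adjusted p = 0.0059), with ETV1 at -1.03 beside SPRED1. Of 5 anti-apoptotic BCL2 family genes 1 departed downward, MCL1 at -0.19 (2 adjusted over the list alone; adjusted p = 0.018). Upward and downward departures in single lines numbered 3 and 19 in A549, 2 and 28 in NCI-H1792, 0 and 7 in NCI-H2122, and 1 and 13 in NCI-H727. These totals of 22, 30, 7 and 14 ranged from 14 to 25, 17 to 31, 3 to 28 and 6 to 12 without any 1 library, were 4, 0 and 63 in A549, NCI-H2122 and NCI-H727 fitted alone, and were 35, 64 and 28 in A549, NCI-H1792 and NCI-H2122 by DESeq2. The upward genes in A549, SERPINB5, CHST6 and TARID, and in NCI-H1792, PRNP and PPL, were named after their values were seen. The score itself departed by -0.95, -1.12, -0.92 and -0.83, with SEs of 0.23, 0.11, 0.20 and 0.06. DESeq2 called 139 genes over the average in place of 65, with 36% of them upward in place of 18.5%.

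The response was compared between lines by an F test of the difference itself. It called 2520 genes with the combination, 1120 with GDC-0973 and 24 with AZ-628. EPHA4, a receptor kinase of the MAPK activity score, rose by 1.12 in A549 and changed by -1.52 in NCI-H727 with the combination. PLK2 rose by 0.35 in A549 and changed by -2.21 in NCI-H727, and MAP2K6 rose by 1.64 in NCI-H1792 and changed by -0.35 in NCI-H727. The change of the MAPK activity score ranged over 1.53 between lines for the combination, 1.39 for GDC-0973 and 0.49 for AZ-628. An exact permutation of line labels, on the summed squared deviations of the line means, gave p = 0.00058, 0.00026 and 0.027. These p-values are too small, since the changes of a line's 3 libraries share the error of its DMSO mean. NCI-H2122 had the smallest fall with the combination and with GDC-0973. For AZ-628 the count of 24 became 13, 14 and 15 without DMSO replicate 1, DMSO replicate 2 and AZ-628 replicate 1 of NCI-H727.

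Across genes, log2 changes with the combination correlated between lines at a Pearson r of 0.05 to 0.25 over all 17981 genes and 0.43 to 0.55 over the 10322 genes with a mean log2 CPM of at least 3. Genes are not independent replicates, so no p is given. Overlaps of calls exceeded those of independent lists in all 6 pairs of lines. These share no libraries but share 1 estimate of spread per gene, so genes that are easier to call can raise such overlaps without a shared response. A549 and NCI-H727 shared 555 rises against 188 and 686 falls against 168, and NCI-H1792 and NCI-H2122 shared 156 rises against 24.8 and 293 falls against 40.5. Genes called up in the first line and down in the second, and the reverse, numbered 89 and 49 for A549 and NCI-H727. For NCI-H1792 and NCI-H2122 they numbered 13 and 8.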

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

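The difference test and its values for single genes were planned. The tests of RNA from another line, of induction, of a hidden batch, of library size, of RNA of other lines along an axis, of a mislabelled library and of other splits of the samples were chosen after the results they bear on were seen.

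The response differed between cell lines, by the F test of the difference itself, for 2520 genes with the combination, 1120 with GDC-0973 and 24 with AZ-628. Named genes stood out where such a gene was called in opposite directions in 2 lines. With the combination, MAP2K6 changed by 1.64 in NCI-H1792 and -0.35 in NCI-H727, TIPARP by 0.48 in NCI-H727 and -0.37 in A549, PLK2 by 0.35 in A549 and -2.21 in NCI-H727, EPHA4 by 1.12 in A549 and -1.52 in NCI-H727, and SERPINB5 by 0.28 in NCI-H1792 and -0.37 in NCI-H727. With GDC-0973, MAP2K6 changed by 0.79 in NCI-H1792 and -0.28 in NCI-H727, PLK2 by 0.32 in A549 and -1.67 in NCI-H727, EPHA4 by 0.87 in A549 and -0.90 in NCI-H727, and ANKRD1 by 0.84 in NCI-H727 and -0.87 in NCI-H1792. The rest involve a line where the gene was at trace level, so that a fitted log2 value there depends on the prior count and is no measure of size. They were TRIM29 (1.31 in NCI-H727, -4.51 in NCI-H1792), FOXL1 (3.35 in NCI-H2122, -0.86 in NCI-H727), ANKRD1 (2.99 in NCI-H2122, -2.31 in NCI-H1792) and GLI2 (3.04 in NCI-H727, -0.32 in A549) with the combination, and GLI2 (1.93 in NCI-H727, -0.33 in A549) with GDC-0973. Of 76 named genes, 47, 34 and 8 differed between lines without calls in opposite directions, with the combination, GDC-0973 and AZ-628. These include genes called in some lines and not in others, so they did not differ in size alone. The change of the MAPK activity score ranged between lines over 1.53, 1.39 and 0.49. A permutation of line labels tested the squared deviations of the line means. Its p-values are too small, since libraries of a line share the error of its DMSO mean.

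Transcripts of another cell line appeared at trace level in the NCI-H1792 combination libraries. RNA or reads of NCI-H727 in these libraries have the values they need, since the median over all 46 NCI-H727-specific genes was 0.413% of the NCI-H727 level in replicate 3 and at most 0.0201% in the 9 libraries of other treatments. Induction by the combination is argued against, since replicate 2, with the same treatment, held 0.0116%, so the neuroendocrine calls in that line may come from NCI-H727 material, by a route that the data do not show. Without trace genes the calls were 2547 in place of 2596 for the combination in NCI-H1792 and 77 in place of 99 against GDC-0973. Such shares stood elsewhere too, at up to 0.522% for A549 in NCI-H727 (combination replicate 2, 7 genes), 0.248% for A549 in NCI-H2122 (GDC-0973 replicate 3, 4 genes), 0.215% for NCI-H2122 in NCI-H1792 (DMSO replicate 3, 17 genes) and 0.171% for NCI-H1792 in NCI-H2122 (combination replicate 3, 16 genes), with no explanation tested.

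Libraries of NCI-H2122 parted along 1 axis inside treatment groups, with 31.1% of the residual variance. An unlabelled batch stays open. Positions are deviations from the mean of each treatment group, so low and high positions within a group balance by construction. Listed from low to high, the 3 libraries of each treatment stood at similar positions on the axis. They were -23.6, 5.1 and 18.6 with DMSO, -23.7, 10.1 and 13.6 with AZ-628 and -21.3, 1.8 and 19.5 with GDC-0973. With both drugs they were -22, 1.3 and 20.7, and blocks of libraries shared by the treatments could give this pattern. As low and high positions in a group are partly built in, the pattern does not decide for such blocks. The first axis of NCI-H1792 had such positions too, as -16.3, -1.1 and 17.5 with DMSO and -15.2, -4.3 and 19.6 with both. A surrogate variable in a line's 12 libraries raised the combination count from 358 to 1488 in NCI-H2122 and 2229 to 4808 in NCI-H1792. It is estimated from the same residuals as the axis, so these rises decide nothing. Library size and RNA of other lines stay open, at a Spearman rho with the axis of -0.39 (permutation p = 0.21; Pearson -0.24, and -0.26 without the 2 farthest libraries) and of 0.13 (permutation p = 0.70; Pearson -0.05, and -0.20). The bound of 0.3 written for excluding a cause was met by 0.13, but the rule was made stricter after these values were seen, because an interval from 12 libraries still reaches 0.6. No biological explanation was tested, and the labels give no batch.

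Few genes were called for GDC-0973 alone in NCI-H2122. A larger spread with changes of the same size is argued against, by a test written before its result was seen. The slope of the NCI-H2122 change on the mean of the other lines was 0.24 (bootstrap interval 0.19 to 0.30, 837 genes). It was 0.82, 0.75 and 0.99 in A549, NCI-H1792 and NCI-H727. The bootstrap drew genes, so its interval leaves out the error between libraries that genes share. Taking genes called in the other lines can lower a slope, and the last 3 slopes use a mean that includes NCI-H2122. With SEs between libraries, the MAPK activity score differed from DMSO by -0.37 ± 0.12 in NCI-H2122. The differences were -1.75 ± 0.17, -1.07 ± 0.10 and -1.57 ± 0.03 in A549, NCI-H1792 and NCI-H727. The presence of 1 DMSO library mislabelled as GDC-0973 is also argued against, since 3 of 3 scored below the DMSO range. A swap with an AZ-628 library stays open. AZ-628 replicate 1 of this line scored 5.64, inside the GDC-0973 range of 5.36 to 5.68, so the test could not see it. A weaker response of this line at 0.1 µM may remain as a hypothesis, beside the open batch above and a lower dose reaching the cells, which was not tested. With the combination the slope was 0.42 in NCI-H2122 and 0.72, 0.68 and 0.95 in the others.

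Other splits of the libraries were counted for each comparison. Every split was fitted with the dispersion trend estimated under the real grouping, so the real and the other splits were not treated fully alike. For 3 against 3 libraries the 10 splits are too few for a share under 0.05, so the real count and the highest of the other splits are given in the order A549, NCI-H1792, NCI-H2122 and NCI-H727. They were 2671 and 50, 2596 and 10, 909 and 6, and 4792 and 0 for the combination against DMSO. For GDC-0973 they were 1111 and 52, 824 and 9, 7 and 40, and 2756 and 0. For AZ-628 they were 0 and 0, 0 and 1, 0 and 131, and 138 and 0. For the combination against GDC-0973 they were 116 and 100, 99 and 13, 116 and 31, and 132 and 0. For the combination against AZ-628 they were 2704 and 1, 2245 and 5, 671 and 96, and 3202 and 2. For GDC-0973 against AZ-628 they were 970 and 0, 784 and 2, 3 and 5, and 1076 and 0. A split of NCI-H2122 with 131 calls where the real one had 0, and one with 40 where it had 7, point to a structure of these samples other than treatment.

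For the averages, 100 relabellings within lines of the drug and DMSO libraries of a comparison were drawn, the real one included. They too reused the dispersion trend of the real grouping. The real count was the largest for the combination (5537 genes, highest other 3103, 1 of 100 as large) and GDC-0973 (2934, highest other 466, 1 of 100). This argues against chance but cannot exclude it, since 1 of 100 is the smallest share possible. Relabelling also takes the libraries of a line as exchangeable, which unlabelled blocks would break. For AZ-628 the real 10 genes were reached by 2 of 100, a share under 0.05, but another relabelling gave 14 and leaving out single libraries gave 5 to 11, so this count is weakly set apart from chance. For the line differences such a relabelling does not measure chance, since a swap of drug and DMSO libraries in 1 line makes a difference of its own. It gave 2520 genes and a highest other of 3023 with the combination (3 of 100 as large), 1120 and 3508 with GDC-0973 (8 of 100), and 24 and 54 with AZ-628 (5 of 100). Nor does it for the departure from additivity, where relabelling the 4 treatments carries the drug effects into the contrast. The counts there were 65 genes and a highest other of 227 on average (2 of 100), 22 and 2502 in A549 (9 of 100), 30 and 454 in NCI-H1792, 7 and 846 in NCI-H2122, and 14 and 2735 in NCI-H727 (10 of 100 in each of these). Relabelling all 4 treatments had first been used for the averages and line differences too, and was replaced for the same reason. It had given highest others of 130, 542 and 414 for the averages with the combination, GDC-0973 and AZ-628 (1, 1 and 2 of 100) and of 1098, 624 and 512 for the line differences (1, 1 and 7 of 100).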

How the results depend on the processing

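The tests with a line's 12 libraries and 1 surrogate variable, with gene IDs that have a symbol, and without trace genes were chosen after the results were seen. No paired analysis was possible from the labels, because replicate numbers only follow the order of records. Unlabelled blocks across treatments were not modelled in the main fit. If present, they count as spread between libraries and may hide changes. Besides the axes of NCI-H2122 and NCI-H1792 above, 1 A549 library of each treatment lay apart on the first residual axis of that line. These stood at 10.4 with DMSO, 16.5 with AZ-628, 22.6 with GDC-0973 and 21.2 with both, and the others at -3.9 or lower. As positions are deviations from group means, a lone library on 1 side of a group is built in, though not the same side in every treatment. No result reversed. All 35 counts stayed within 1.5 times of their value with no filter, with symbol-only IDs and without trace genes, and so did the MAPK activity score calls with a prior count of 0.5, RLE scaling, the median or any 1 gene left out. Named genes lost calls in 2 cases with RLE scaling, 3 with DESeq2, 4 with a surrogate variable, 4 with no filter, 6 in a line's own 12 libraries and 6 there with a surrogate variable. List calls were the same in 740 cases and gained in 156 with a preset correlation, and 771, 123 gained and 2 lost with fry. A share of genes with small changes lies below what 3 libraries per group can show, since 1.5-fold changes were recovered in 48.5 to 75.0% of simulated cases. The cause was not tested for the changes below, except that a line's own fit uses that line's spread (median gene SD 0.09 in NCI-H727, 0.14 in NCI-H2122) and fewer libraries.

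RLE scaling gave 1 call in place of 3 for GDC-0973 against AZ-628 in NCI-H2122. With 1 surrogate variable over 48 libraries, the combination against GDC-0973 in NCI-H727 gave 269 in place of 132 and the departure from additivity in NCI-H2122 16 in place of 7. DESeq2 gave 14 in place of 0 for AZ-628 in NCI-H1792, 220 in place of 138 in NCI-H727 and 24 in place of 10 on average. It gave 11 in place of 7 for GDC-0973 in NCI-H2122, and 190, 173 and 264 in place of 116, 99 and 132 for the combination against GDC-0973 in A549, NCI-H1792 and NCI-H727. For the departure from additivity it gave 35, 64 and 28 in place of 22, 30 and 7 in A549, NCI-H1792 and NCI-H2122, and 139 in place of 65 on average.

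A fit of NCI-H2122 alone gave 358 in place of 909 for the combination, 0 in place of 7 for GDC-0973, 20 in place of 116 for the combination against GDC-0973, 253 in place of 671 against AZ-628, 0 in place of 3 for GDC-0973 against AZ-628 and 0 in place of 7 for the departure from additivity. For NCI-H727 alone these were 4413 in place of 2756 for GDC-0973, 490 in place of 138 for AZ-628, 991 in place of 132 and 5465 in place of 3202 for the combination against GDC-0973 and AZ-628, 2465 in place of 1076 for GDC-0973 against AZ-628 and 63 in place of 14 for the departure, which in A549 was 4 in place of 22. With 1 surrogate variable added, the combination gave 4808 in NCI-H1792, 1488 in NCI-H2122 and 7535 in NCI-H727. GDC-0973 gave 2682, 11 and 6045 there, and AZ-628 gave 1 in NCI-H1792 and 1123 in NCI-H727. The combination against GDC-0973 gave 354, 255, 313 and 1522 in A549, NCI-H1792, NCI-H2122 and NCI-H727, and against AZ-628 3954, 1241 and 5961 in the last 3. GDC-0973 against AZ-628 gave 1561, 2013, 0 and 4044, and the departure 48, 99, 34 and 212, in the 4 lines.

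The share of calls that were rises moved by over 10 points in some cases. For the combination against GDC-0973 it went from 28.8% to 43.1% (1 surrogate variable), 50.1% (own fit), 45.1% (DESeq2) and 46.4% (own fit, surrogate variable) in NCI-H727, from 36.2% to 52.5% (own fit, surrogate variable) in A549, from 32.3% to 11.9% in NCI-H1792 and from 18.1% to 0% in NCI-H2122 (own fits). For GDC-0973 against AZ-628 in NCI-H727 it went from 26.1% to 36.9% and 41.2% (own fits without and with a surrogate variable), and for the combination against AZ-628 in NCI-H1792 from 50.6% to 40.5% (own fit). For the departure it went from 6.67% to 21.9% in NCI-H1792 (DESeq2), from 7.14% to 30.2%, 25% and 34.4% in NCI-H727, from 18.5% to 36% on average (DESeq2) and from 13.6% to 0% in A549 (own fit).

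Pearson correlations of combination changes between lines (0.11, 0.17, 0.25, 0.05, 0.14 and 0.13, in the order A549 with NCI-H1792, NCI-H2122 and NCI-H727, NCI-H1792 with NCI-H2122 and NCI-H727, NCI-H2122 with NCI-H727) became 0.32, 0.28, 0.35, 0.28, 0.28 and 0.35 as Spearman's, and 0.51, 0.44, 0.51, 0.49, 0.43 and 0.55 over genes with a mean log2 CPM of at least 3.

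Leaving out single libraries moved some counts by over 1.5 times; each range is followed by those libraries (D DMSO, A AZ-628, G GDC-0973, C combination, with the replicate number). For GDC-0973 the ranges were 655 to 1047 in A549 (G1 655), 515 to 694 in NCI-H1792 (G1 515, D2 535) and 1 to 6 in NCI-H2122 (D1 4, G1 4, G2 1). For the combination in NCI-H2122 the range was 567 to 777 (C3 567, D3 584), and for AZ-628 in NCI-H727 72 to 95 (D2 73, D3 76, A1 72, A2 84, A3 80). For the combination against GDC-0973 they were 36 to 138 in A549 (G2 36, G3 76, C2 67), 44 to 138 in NCI-H1792 (C1 58, C3 44, G1 57, G2 46, G3 58), 46 to 167 in NCI-H2122 (C2 74, G1 46) and 67 to 178 in NCI-H727 (C2 74, C3 68, G2 67, G3 83), and against AZ-628 1791 to 2381 in A549 (A2 1791), 392 to 660 in NCI-H2122 (A3 392) and 2072 to 3452 in NCI-H727 (C3 2072). For GDC-0973 against AZ-628 they were 632 to 949 in A549 (G1 632, A3 640), 481 to 630 in NCI-H1792 (G3 481), 0 to 2 in NCI-H2122 (G1 1, G2 0, G3 0, A3 1) and 687 to 778 in NCI-H727 (A2 695, G3 687). For the departure they were 14 to 25 in A549 (D1 14, G2 14), 17 to 31 in NCI-H1792 (C1 17, D1 18), 3 to 28 in NCI-H2122 (D1 26, D2 3, C2 4, G1 4, G3 28, A1 20, A3 4) and 6 to 12 in NCI-H727 (D1 8, D2 9, D3 9, C3 6, G2 8, A3 8). The AZ-628 average gave 5 to 11 (5 without D1 of NCI-H2122, A2 of A549, A1 or A2 of NCI-H1792 or D1 of NCI-H727, and 6 without D2 of NCI-H2122 or A2 or A3 of NCI-H727), and AZ-628 line differences 13 to 27 (NCI-H727 D1 13, D2 14, A1 15). The AZ-628 score difference was -0.18 to -0.13, with an exact permutation p above 0.05 without A1 of A549 (0.051) or A1 (0.066) or D1 (0.058) of NCI-H2122. All other ranges of counts lay within 1.5 times, such as 5139 to 5726 for the average combination and 44 to 90 for the average departure.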

Other observations

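The aryl hydrocarbon receptor was the subject of a test written before its result was seen, and the SE it uses was recomputed from library means afterwards. The gene list tests were planned.

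The remaining gene lists described other parts of the response to the combination, averaged over the lines. Of 15 interferon-stimulated genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.44), with the antiviral proteins IFIT1 at 1.46 and IFIT2 at 0.75 and OAS1 at -0.18. Of 12 MHC class I presentation genes 4 rose (7 adjusted over the list alone; adjusted p = 0.55 with an estimated correlation and 0.023 with a preset one), among them the immunoproteasome subunit PSMB9 (0.49) and TAPBP (0.23). Of 16 lysosome and autophagy genes 7 rose and none fell (8 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with the autophagy kinase ULK1 at 0.80 and GABARAPL1 at 0.58. Of 12 epithelial genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.65), with CLDN3 at 0.52, CDH1 at 0.28 and KRT18 at -0.54. Among 11 mesenchymal genes CDH2 rose (0.51) and ZEB1 fell (-0.40), 1 and 1 also adjusted over the list alone (adjusted p = 0.89). Of 10 alveolar and foregut genes HNF4A (1.49) and FOXA1 (0.24) rose (2 adjusted over the list alone; adjusted p = 0.44). Of 10 neuroendocrine genes CHGA (0.66) and DDC (0.44) rose and SCG2 fell (-0.70), 2 and 1 also adjusted over the list alone (adjusted p = 0.89). In NCI-H1792 7 of these rose (8 adjusted over the list alone; adjusted p = 0.26), all 10 being trace genes there. The average rise of CHGA leans on that line, where it had 8 counts with DMSO and 55 with the combination (ratio 7.08). Its ratios were 0.941 in A549 and 1.25 in NCI-H2122. The NCI-H1792 combination libraries are those with raised NCI-H727 transcripts. CDH1, CDH2, ZEB1, HNF4A, CHGA, DDC and SCG2 were at trace level in at least 1 line, so that their averages include changes near the floor of counting.

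None of the metabolic and stress lists passed its test for the combination averaged over the lines. Of 13 glycolysis genes 4 fell (4 adjusted over the list alone; adjusted p = 0.58), with the hexokinase HK2 at -0.77 and PFKP at -0.22. Of 15 cholesterol synthesis genes 6 rose and 1 fell (7 and 3 adjusted over the list alone; adjusted p = 0.77), with INSIG1 at 0.38 and LSS at 0.28. Of 12 integrated stress response genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.90), with DDIT4 at 0.37, TRIB3 at -0.43 and CHAC1 at -0.37 beside ATF3. Of 10 NRF2 targets 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.79), with HMOX1 at 0.75, AKR1C1 at 0.29, SLC7A11 at -0.44 and AKR1B10 at -0.27. With GDC-0973 alone in A549, 6 of the 10 rose (6 adjusted over the list alone; adjusted p = 0.0089). Of 12 p53 targets 4 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.77), with DDB2 at 0.43, SESN1 at 0.31, GDF15 at -0.68 and AEN at -0.65. AKR1C1 and AKR1B10 in NCI-H727 and GDF15 in NCI-H1792 were at trace level. Of the 8 mitochondrial genome genes none was called on average (0 adjusted over the list alone; adjusted p = 0.97). In A549 4 rose (8 adjusted over the list alone), with a median log2 change of 0.82 and an adjusted p = 0.38. In NCI-H1792 none was called over all genes (7 falls adjusted over the list alone), with a median of -0.66 and an adjusted p = 0.49. Of 6 fibroblast markers LUM, at trace level in all lines but NCI-H1792, was called upward at 0.67 (0 adjusted over the list alone; adjusted p = 0.77), and of 3 immune cell and 4 brain cell markers tested none was called (0 and 0 adjusted over the lists alone; adjusted p = 0.79 and 0.89).

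CYP1B1 and TIPARP, both targets of the aryl hydrocarbon receptor, were higher with AZ-628 alone on average. The hypothesis that this reflects a response of that receptor's targets was tested on the others among them, CYP1A1 (0.38 ± 0.32), ALDH3A1 (0.19 ± 0.12) and AHRR (0.14 ± 0.07), none of them called by edgeR (adjusted p = 1, 1 and 0.96). CYP1A1 was at trace level in A549 and NCI-H1792, and ALDH3A1 in NCI-H727. Their mean was 0.24 with an SE of 0.14, and the mean minus 2 SEs was -0.04, so that the hypothesis stays undecided. With the SE first computed, 0.12, which took the genes as independent, the interval of 2 SEs would have lain just above 0 and the test would have come out for the hypothesis.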
